A study of Solanum lycopersicum with 17 samples.

How the data were processed

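RNA from floral buds of a male-sterile tomato line (ms1035) and a male-fertile line (T-1082) was extracted with TRIzol and made into RNA-seq libraries, per the labels. Both lines were sampled at 3 developmental stages, which the labels number without defining them. The labels call the samples biological replicates. A total of 17 libraries were analysed: 3 at each of 3 stages of the sterile line, 2 at stage 1 of the fertile line (replicates 2 and 3), and 3 at stages 2 and 3 of the fertile line. Replicate 1 of fertile stage 1 is not analysed here.

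Per the file headers, each deposited table gives counts for 34727 gene models in 2 columns, all reads assigned to a gene and those assigned uniquely, and both columns hold whole numbers. Each table also gives RPKM per the file headers (reads scaled by gene length and library total), and 0 values differed from the number computed from the total reads by more than 1e-06 of their size. The gene length column of the deposited tables holds another kind of value, bases per gene model. All but 1 of the 34727 lengths (34726) are multiples of 3, so they are coding lengths. The aligner, the counting program and the strandedness of the count are not given in the sources used here. The genome build is named only within 2 of the gene model names, as SL2.40. Each table belongs to 1 sample, and 0 columns belonged to other samples.

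Counts of all assigned reads were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 6 groups of line and stage, which left 13568 genes and at least 97.0% of each library's reads. TMM factors lay between 0.901 and 1.09. All 17 libraries entered 1 quasi-likelihood fit with 1 coefficient per group and 11 residual degrees of freedom. The common dispersion was 0.0844, a biological coefficient of variation of 0.291. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Counts at an unadjusted p under 0.05 are also given, and without any change a share of 0.05 of the 13568 genes is expected there. Contrasts compared sterile with fertile buds at each stage, stage 2 with stage 1 and stage 3 with stage 2 in each line, and an F-test over 2 interaction contrasts asked whether the line difference depends on stage. Levels are CPM, the reads of a gene scaled to the total of assigned reads of the library. Fold changes are log2 values of the first group over the second. Their SE is the size of the log2 value divided by the square root of the quasi-likelihood F statistic. The p-values measure only the spread between the samples.

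A group with 0 reads is treated as at most 3 reads over the whole group, and a fold against it is a lower bound. With 1 to 3 reads in a group, the ratio of summed reads is given with an exact 95% binomial interval. These bounds and intervals cover counting error only, not the spread between libraries, since reads were summed over each group. The reads carry no molecular identifiers, so counting error itself may be understated.

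The 10 gene lists hold 79 gene identifiers with names recalled from the tomato literature. They were fixed before the data were examined, as were the groups, the tests, the comparisons, the rule for naming genes and the settings to be varied. Neither the deposited tables nor the RefSeq annotation pairs the identifiers with names: 0 RefSeq entries hold an identifier of this kind. Names were therefore checked by position only. Of the 79 list genes, 42 had a symbol in RefSeq, and 42 of the 42 lie on the same chromosome there. In relative gene order along the chromosome 41 of the 42 lie within 5% and the largest difference was 7.73%. The other 37 names could not be checked in this way. The names of the pair of PISTILLATA-type genes were exchanged in the list as fixed, so they are given here by identifier. Further lists made of patterns on product descriptions were not used, since only 2 gene models of the tables carry a description. The list of tapetum and anther opening genes is mixed: beside tapetum genes it holds a polygalacturonase gene, which was not tested, and the invertase genes LIN5 and LIN7. The lists of anther regulators and of tapetum and anther opening genes draw in part on published work on mutants of this locus.

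Lists with at least 5 tested genes (8 of 10) were compared with all other tested genes by limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of each stage. The same test was run with a correlation estimated per list. The rule for named genes took Ms10 first, then each anther regulator, and up to 4 called members of each other list. Where a list had no called member, it took the 2 with the highest mean level. For each comparison it added up to 2 unnamed identifiers each way with the largest change among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups.

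Whether replicate numbers pair the samples was tested from the correlation of residuals between samples with the same number. For stage 3 against stage 2 the correlations were 0.19, 0.28 and 0.32 in the fertile line and 0.36, 0.37 and 0.46 in the sterile line. There 6 of 6 libraries in each line were closest to the library with their own number. Stages 1 and 2 of the fertile line share only 2 numbers, fewer than the 3 pairs the rule asks for. In the remaining planned comparisons at least 1 such correlation was below 0.1. Stage 3 against stage 1 was not tested in this way. Fits with the replicate number as a block are therefore given beside the stage 3 against stage 2 results. They are also given for stages 1 and 2 of sterile buds, where the correlations were 0.354, 0.0734 and 0.547.

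The settings chosen to be varied were size factors from DESeq2 1.42.0, its own tests, no low-count filter, only the libraries compared, uniquely assigned reads, a replicate block, a minimum change of 2-fold, limma on log2 RPKM with a pseudocount of 1 or 0.1, and leaving out each library in turn. Leaving out either of the 2 fertile stage 1 libraries leaves a lone library there, which is assumed to vary like the other groups in every comparison that uses it. Added after the data were seen were a block within each line, leaving out the sterile libraries numbered 3, thinning all libraries to 499608 reads, stage 3 against stage 1, and the line difference averaged over stages. The calling procedure was tested on simulated counts with known changes for the stage 2 line comparison, in 3 runs with 200 changed genes each. It recovered 60.0% of genes made 4-fold lower and 90.7% of those made 4-fold higher, 10.7% and 20.0% at 2-fold, and 84.0% and 100.0% at 16-fold. Between 1.52% and 3.52% of its calls were false, and a comparison without change gave 0 calls by edgeR. Every simulated gene had a dispersion of 0.08, libraries were independent, and changed genes had a mean of at least 5 CPM. These rates therefore need not hold for genes that spread more, or for replicate sets that vary together. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.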

Results

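Floral buds of male-sterile (ms1035) and male-fertile (T-1082) tomato were compared by RNA sequencing at 3 stages. Each group held 3 libraries, except fertile buds at stage 1 with 2. Libraries held 499608 to 817548 assigned reads, with means of 613553 in sterile and 686233 in fertile buds, and 18089 to 19320 genes had reads. Between 98.7% and 99.5% of reads were assigned uniquely, and the 10 most abundant genes took 3.38% to 6.26% of reads. A sterile group without reads for a gene allowed up to 1.54, 1.58 and 1.79 CPM at stages 1, 2 and 3. The first principal component held 29.6% of the variance. On the third, with 12.6%, libraries numbered 3 lay to 1 side in both lines: the sterile ones at -32.0, -59.5 and -37.6, against -6.23 to 31.8 in the other 6 sterile libraries, and the fertile ones at -19.7, -12.9 and -19.2, against -3.56 to 23.6 in the other 5 fertile libraries.

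Ms10 (Solyc02g079810), a bHLH gene needed for tapetum development and the gene named for the ms10 locus, was read in fertile buds at stage 1 at 32.9 ± 6.22 CPM (mean ± SD, n = 2), reads scaled to the total of the library. Replicates 2 and 3 held 28 and 17 reads, and each of the 3 sterile libraries of that stage held 0. Ms10 was at least 21.8-fold lower in sterile buds (edgeR quasi-likelihood, adjusted p = 0.0382). At stage 2, 1 fertile and 1 sterile library held 2 reads each and the other 4 held none. At stage 3 all 6 libraries held 0 reads, so no difference was detectable at this depth. The stage 1 call was lost in edgeR when any of the 5 libraries was left out: adjusted p was 0.102, 0.158 and 0.118 without sterile replicates 1, 2 and 3, and 0.190 and 0.0766 without fertile replicates 2 and 3. Over the 14 alternatives it ranged from 0.000282 to 0.190.

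Further regulators of the anther were also lower in sterile buds. AMS (Solyc08g062780), a bHLH regulator of tapetum function, had 466 ± 70.5 (n = 2), 373 ± 196 (n = 3) and 86.1 ± 68.1 (n = 3) CPM in fertile buds at stages 1, 2 and 3. The 9 sterile libraries together held 0, 1 and 1 reads at these stages. AMS was at least 307-fold lower at stage 1 (edgeR adjusted p = 0.000166), the read ratio was 687 at stage 2 (95% interval 123 to 2.72e+04, edgeR adjusted p = 0.000247) and 162 at stage 3 (28.8 to 6446, edgeR adjusted p = 0.00804). TDF1 (Solyc03g113530), a MYB gene of tapetum development, fell from 46.1 ± 27.4 CPM (n = 2) in fertile to 0 in sterile buds at stage 1, at least 28.5-fold (edgeR adjusted p = 0.0363). At stage 2 it stood at 26.1 ± 23.3 against 1 read, and did not pass (edgeR adjusted p = 0.0606). The lines overlapped there, with 1.22 CPM in fertile replicate 2 and 1.70 in sterile replicate 1.

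The other 3 regulators did not pass at any stage by edgeR over all genes. Ms32 (Solyc01g081100), a bHLH gene, stood at 121 ± 1.80 CPM in fertile and 13.7 ± 17.3 in sterile buds at stage 1 (edgeR adjusted p = 0.0856). MS1 (Solyc04g008420) had 53.3 ± 62.2 and MYB80 (Solyc10g005760) 21 ± 20.2 in fertile buds of stage 1, and both had 0 sterile reads (edgeR adjusted p = 0.139 and 0.225). At stage 2 they had 80 and 65 fertile reads, of which replicate 2 held 2 and 0, and again 0 sterile reads. Of the 6 regulators tested, 3, 1 and 1 were lower at stages 1, 2 and 3 over all genes, and 6, 5 and 1 when adjusted over the list alone. The list was lower by camera at stage 1 (adjusted p = 2.6e-13, and adjusted p = 0.00654 with an estimated correlation). At stage 2 camera gave adjusted p = 1.35e-06, but adjusted p = 0.0711 with an estimated correlation, and at stage 3 0.0211, but adjusted p = 0.381 with an estimated correlation. Because the list draws in part on work on this locus, its direction is not independent evidence. The stage 1 call of TDF1 was lost without any 1 of the sterile replicates or fertile replicate 3, and the stage 3 call of AMS without sterile replicate 2 or without all sterile libraries numbered 3. Over the alternatives the edgeR, DESeq2 or limma adjusted p of these calls ranged from 7.74e-05 to 0.155 and from 5.82e-07 to 0.0610.

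**Figure D1:**
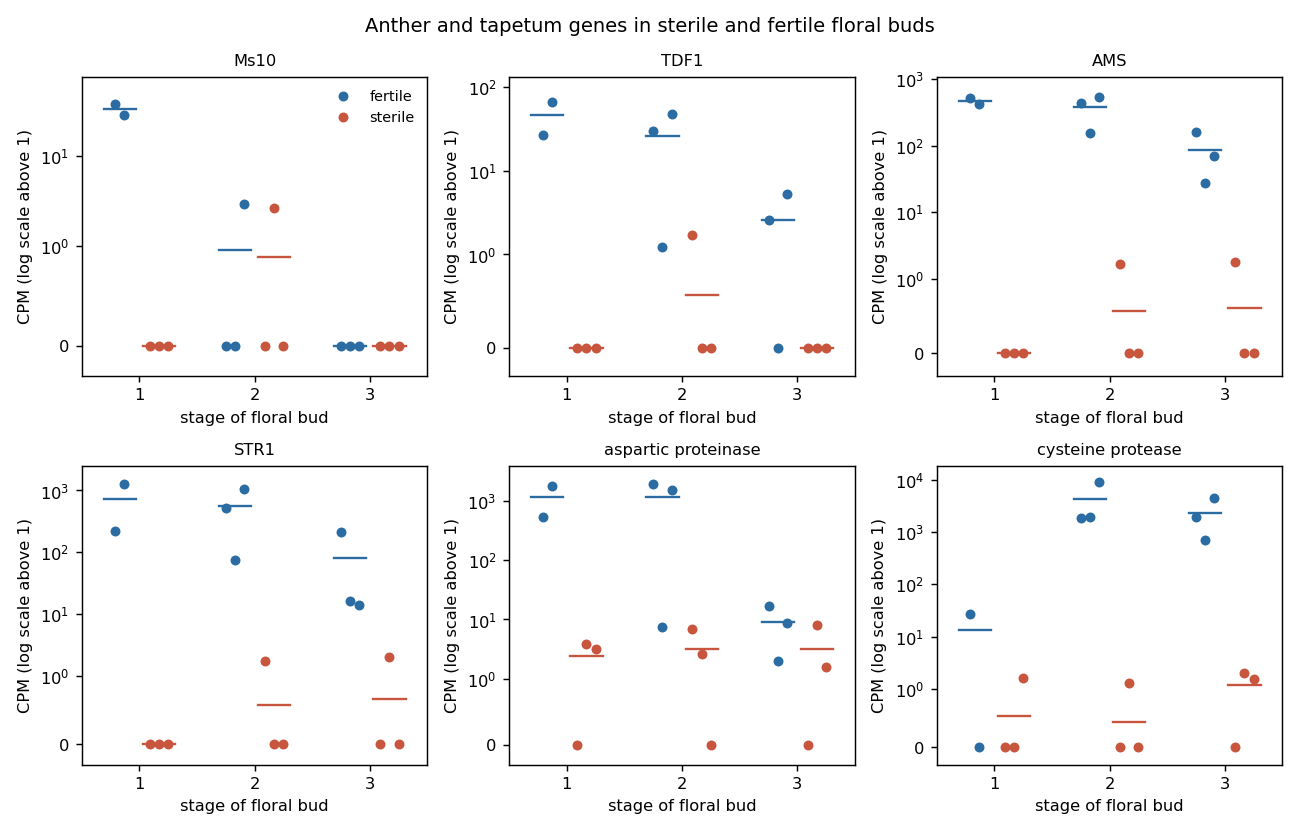
CPM (vertical axis, logarithmic above 1 and linear below) of 6 anther and tapetum genes at stages 1, 2 and 3 (horizontal axis) in fertile (blue) and sterile (red) buds. Points are libraries and short lines are group means; AMS stands at group means of 86.1 to 466 in fertile buds and 0 to 0.612 in sterile buds.

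At stage 1, the comparison asks which genes differ between sterile and fertile buds at the first stage sampled. Among genes of the tapetum, the cell layer that feeds developing pollen, 3 were lower. TomA108 (Solyc01g009590), an anther-specific protein gene, had 788 ± 540 CPM (n = 2) in fertile buds and 0 reads in sterile ones, at least 484-fold lower (edgeR adjusted p = 0.0013). STR1 (Solyc03g053130), a gene of the tapetum list, had 737 ± 728 against 0 reads, at least 441-fold lower (edgeR adjusted p = 0.00624). An aspartic proteinase gene (Solyc06g069220) had 1169 ± 896 against 2.39 ± 2.10, a log2 difference of -8.80 (SE 1.51, edgeR adjusted p = 0.00575). For each of these 3 genes the 3 sterile libraries lay below both fertile ones.

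The list of tapetum and anther opening genes also holds the invertase genes LIN5 and LIN7. Of its 6 members tested at stage 1, 3 were lower over all genes and 4 when adjusted over the list alone (camera adjusted p = 4.67e-07, and 0.00654 with an estimated correlation). Floral organ identity genes as a list were lower by camera (adjusted p = 0.0283), but adjusted p = 0.367 with an estimated correlation, and 0 of 8 passed singly over all genes or when adjusted over the list alone. Solyc08g067230, a PISTILLATA-type gene of petal and stamen identity, stood at 241.1 ± 18.8 CPM in sterile and 346 ± 44.6 in fertile buds, and TAG1 (Solyc02g071730), the AGAMOUS-type gene of stamen and carpel identity, at 164 ± 14.5 and 226 ± 51.3. The flavonoid and anthocyanin list did not pass camera (adjusted p = 0.229), with 0 of 9 members called over all genes and 1 higher when adjusted over the list alone. Its most abundant members CHS2 (Solyc05g053550), a chalcone synthase gene, and FLS (Solyc11g013110), a flavonol synthase gene, stood at 638 ± 97.6 against 754 ± 155 and 456 ± 8.44 against 488 ± 17.2. In the jasmonate and wound list 0 of 14 members passed either way, and camera gave adjusted p = 0.0661. With a replicate block camera gave adjusted p = 0.0137 (lower), but 0.459 with an estimated correlation. Its most abundant members, the threonine deaminase gene TD (Solyc09g008670) and the prosystemin gene (Solyc05g051750), stood at 420.1 ± 564 CPM in sterile against 682 ± 536 in fertile buds and at 408 ± 101 against 542 ± 45.8.

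Over all tested genes at stage 1, 158 were called by edgeR, 10 higher and 148 lower in sterile buds, and 34 of the 148 had 0 reads in the sterile libraries. Solyc07g015960 was lower by at least 834-fold (1289 ± 92.5 CPM against 0 reads) and Solyc02g080760 by at least 950.0-fold (1630 ± 2102 against 0 reads). Among higher genes, the read ratio was 75.2 for Solyc01g102570 (13.2 to 2995) and 71.7 for Solyc08g080620 (12.6 to 2859). Only 89 of the 109 sterile reads of Solyc01g102570 were unique, so its level is uncertain. The count was 77, 54 and 59 without sterile replicates 1, 2 and 3 in turn, and 59 without all sterile libraries numbered 3. The call of STR1 was lost without the latter, that of Solyc02g080760 without any 1 sterile replicate or fertile replicate 3, that of the aspartic proteinase gene without sterile replicate 2, and that of Solyc08g080620 without fertile replicate 2. Over the alternatives their adjusted p reached 0.0582, 0.139, 0.0671 and 0.175 in that order.

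At stage 2, 4 genes of the tapetum and anther opening list were lower in sterile buds. A cysteine protease gene (Solyc07g053460) had 4330 ± 4245 CPM in fertile buds (n = 3) and 1 read in the sterile libraries, a read ratio of 7804 (1400 to 3.08e+05, edgeR adjusted p = 0.000234). STR1 had 556 ± 498 against 1 read, a ratio of 1003 (179.6 to 3.96e+04, edgeR adjusted p = 0.00507). TomA108 had 579 ± 443 against 0 reads, at least 351-fold lower (edgeR adjusted p = 0.00128). The aspartic proteinase gene had 1156 ± 1016 against 3.15 ± 3.42, a log2 difference of -8.51 (SE 1.45, edgeR adjusted p = 0.00308). Fertile replicate 2 stood apart from replicates 1 and 3 in part of these genes: the aspartic proteinase gene had 7.34 CPM there against 1936 and 1526, close to the 6.79 of sterile replicate 1, and TomA108 had 89.3 against 695 and 952. Of the 6 members tested, 4 were lower over all genes and 5 when adjusted over the list alone (camera adjusted p = 7.65e-12, and 0.00111 with an estimated correlation). The call of the aspartic proteinase gene did not pass in limma with a pseudocount of 0.1 (adjusted p = 0.0702).

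Of the 8 floral organ identity genes tested at stage 2, 2 were lower over all genes and 4 when adjusted over the list alone (camera adjusted p = 6.02e-04, but adjusted p = 0.111 with an estimated correlation). The PISTILLATA-type gene Solyc08g067230 had 800 ± 254 CPM in fertile and 343 ± 38.7 in sterile buds (n = 3 each), a log2 difference of -1.25 (SE 0.28, edgeR adjusted p = 0.0216). TAG1 had 589 ± 188 against 269 ± 36.5, a log2 difference of -1.15 (SE 0.26, edgeR adjusted p = 0.0239). Of 9 flavonoid and anthocyanin genes, 2 were higher over all genes and 2 when adjusted over the list alone (camera adjusted p = 0.0284, but adjusted p = 0.0721 with an estimated correlation). DFR (Solyc02g085020), the dihydroflavonol reductase gene, had 17.2 ± 7.20 in sterile against 1.29 ± 1.23 in fertile buds, a read ratio of 12.9 (4.03 to 65.7, edgeR adjusted p = 0.0283). AN2 (Solyc10g086250), a MYB activator of anthocyanin synthesis, had 25.2 ± 5.02 against 4.82 ± 4.88, a log2 difference of 2.30 (SE 0.52, edgeR adjusted p = 0.0216). For each of these 4 genes the 3 sterile libraries lay beyond all 3 fertile ones.

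**Figure D2:**
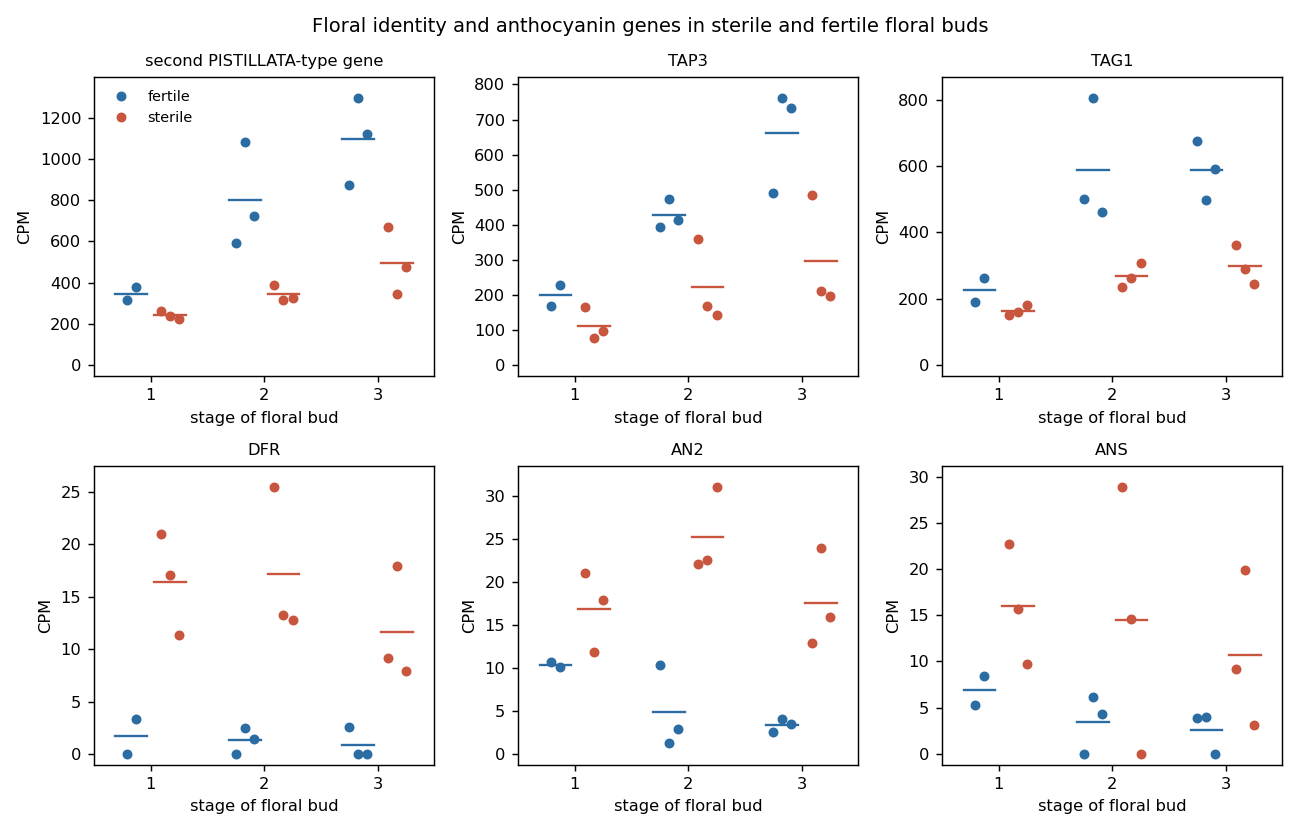
CPM (vertical axis) of 3 floral organ identity genes (top) and 3 anthocyanin genes (bottom) at stages 1, 2 and 3 (horizontal axis) in fertile (blue) and sterile (red) buds. Points are libraries and short lines are group means; TAG1 means at stage 2 are 589 in fertile and 269 in sterile buds, and AN2 means are 4.82 and 25.2.

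In the jasmonate and wound list ARG2 (Solyc01g091170), a wound-inducible arginase gene, was higher in sterile buds at stage 2 with 399 ± 302 against 66.5 ± 15.8 CPM, a log2 difference of 2.58 (SE 0.61, edgeR adjusted p = 0.0283), though the libraries of the lines overlapped. It was the only 1 of 14 called over all genes or over the list alone, and the list did not pass camera (adjusted p = 0.888). In total edgeR called 384 genes at stage 2, 82 higher and 302 lower, and 45 of the 302 had 0 sterile reads. Solyc02g078370 had 8042 ± 4564 in fertile buds against 2 sterile reads, a ratio of 7428 (2056 to 6.13e+04), and Solyc03g051960 was at least 758-fold lower. Solyc09g059030 and Solyc04g082910 were at least 29.4-fold and 26.9-fold higher, with 0 reads in the fertile libraries. The count was 177 and 164 without sterile replicates 1 and 2 and 249 without fertile replicate 1. The call of the PISTILLATA-type gene was lost without sterile replicate 1, 2 or 3 or fertile replicate 2, and that of TAG1 without sterile replicate 1 or 2 or fertile replicate 2. The call of DFR was lost without sterile replicate 1 or 2 or any fertile replicate, that of AN2 without sterile or fertile replicate 2 or 3, and that of ARG2 without sterile replicate 1 or 3 or any fertile replicate. Over the alternatives the adjusted p of these 5 calls reached 0.120, 0.139, 0.142, 0.0957 and 0.167.

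At stage 3, the cysteine protease gene remained lower, with 2356 ± 1893 CPM in fertile buds against 2 sterile reads (n = 3 each), a ratio of 1994 (552 to 1.65e+04, edgeR adjusted p = 0.000713). It was the only 1 of 6 tested members of the tapetum and anther opening list past the threshold over all genes, and 5 passed when adjusted over the list alone (camera adjusted p = 1.29e-08, and 0.00432 with an estimated correlation). The floral identity list was lower by camera (adjusted p = 2.84e-06, and 0.0402 with an estimated correlation), with 0 of 8 called over all genes and 4 when adjusted over the list alone. Solyc08g067230 stood at 495 ± 164 in sterile against 1096 ± 213 in fertile buds, and TAP3 (Solyc04g081000), a petal and stamen identity gene, at 297.5 ± 162 against 662 ± 149. The flavonoid and anthocyanin list was higher (camera adjusted p = 2.79e-04, and 0.00788 with an estimated correlation), with 0 of 9 called over all genes and 4 when adjusted over the list alone. Its most abundant members are named here for their level, not for the size of their change. CHS2 stood at 751 ± 125 in sterile against 658 ± 37.8 in fertile buds, and the flavanone hydroxylase gene F3H (Solyc02g083860) at 605 ± 44.6 against 512 ± 21.7.

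At stage 3 edgeR called 100 genes, 23 higher and 77 lower, and 16 of the 77 had 0 sterile reads. Solyc02g078370 had 4119 ± 3049 in fertile buds against 2 sterile reads, a ratio of 3510 (971 to 2.90e+04). Solyc09g059030 and Solyc04g082910 were at least 30.3-fold and 13.3-fold higher, again with 0 fertile reads, and their calls were lost without fertile replicate 1, 2 or 3 or sterile replicate 3, and also without sterile replicate 1 and 2, respectively. Over the alternatives the adjusted p of these 2 calls reached 0.136 and 0.159. The count was 13 and 35 without sterile replicates 2 and 3, 65 and 25 without fertile replicates 2 and 3, 28 without all sterile libraries numbered 3, and 179 with DESeq2. In the jasmonate and wound list 0 of 14 members passed over all genes or over the list alone (camera adjusted p = 0.213). TD stood at 6579 ± 4464 in sterile against 9678 ± 2715 in fertile buds.

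Between the lines at each stage, no member was called in the lists of reference, alkaloid, heat stress and gibberellin genes. Of 8 reference genes, 8 steroidal alkaloid genes, 5 heat stress genes and 2 gibberellin genes tested, 0 were called at any stage by edgeR over all genes or adjusted over the list alone. Camera adjusted p at stages 1, 2 and 3 was 0.497, 0.603 and 0.503 for reference genes, 0.439, 0.314 and 0.537 for alkaloid genes and 0.22, 0.174 and 0.503 for heat stress genes. At stage 2, the elongation factor gene EF1a (Solyc06g005060) stood at 2332 ± 307 CPM in sterile and 1881 ± 204 in fertile buds, and GAPDH (Solyc05g014470) at 951 ± 33.7 and 883 ± 146. Of the alkaloid genes GAME11 (Solyc07g043420) stood at 4619 ± 816 and 6047 ± 1002, and GAME12 (Solyc12g006470) at 1057 ± 299 and 1232 ± 166. Of the heat stress genes HSP101 (Solyc03g115230) stood at 179 ± 106 and 272 ± 91.4, and HSP17 (Solyc06g076520) at 90.5 ± 7.66 and 162 ± 23.8. The gibberellin signalling repressor PROCERA (Solyc11g011260) had 240.1 ± 20.2 CPM in sterile and 168 ± 52.2 in fertile buds, with a log2 difference of 0.47 (SE 0.25). The list of late pollen genes held LAT52 (Solyc10g007270), which fell below the low-count filter.

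Of the genes lower in sterile buds, 97 were called at both stages 1 and 2 and 58 at both stages 2 and 3, against 3.29 and 1.71 expected from independent calls. Libraries with the same number varied together across stages 2 and 3 in each line, so the calls are not independent and these numbers do not test the overlap. In all, 372 genes were lower and 95 higher at 1 stage or more, and 0 were called in both directions by edgeR. The 372 genes took 5.04 ± 1.66% (n = 2), 7.38 ± 2.64% and 4.15 ± 0.715% of reads in fertile buds at stages 1, 2 and 3, and 0.823 ± 0.0145%, 0.844 ± 0.0306% and 1.19 ± 0.176% in sterile buds (n = 3 each). They peaked in fertile buds at stage 1 for 133 genes, at stage 2 for 170 and at stage 3 for 69. These shares belong to genes chosen by the same comparison. Whether a line difference depends on stage was tested directly, and edgeR called 0 genes, DESeq2 14, and limma 6 or 1 with a pseudocount of 1 or 0.1. In edgeR 365 genes had an unadjusted p under 0.05, fewer than expected without any change. A gene called at 1 stage and not at another is therefore not shown to differ between them. For genes with 0 reads in whole groups the edgeR test can fail, so its 0 calls do not speak to them. MS1 had 0 reads in both lines at stage 3 and in sterile buds at stage 2, so a shift of its line difference between these stages could not be measured.

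Between stages 1 and 2 of fertile buds, the cysteine protease gene Solyc07g053460 rose from 13.3 ± 18.9 (n = 2) to 4330 ± 4245 CPM (n = 3), a log2 change of 8.37 (SE 1.20, edgeR adjusted p = 0.00902). Solyc03g098680 rose from 0 reads to 2143 ± 2324 CPM, at least 908-fold. Solyc03g119620 fell from 69.2 ± 7.69 to 0.911 ± 0.792, a read ratio of 79.8 (21.5 to 668), and Solyc06g073750 fell from 240.1 ± 80.8 to 10.4 ± 5.45, a log2 change of -4.45 (edgeR adjusted p = 0.0481). In total 13 genes rose and 8 fell, 21 in edgeR, against 72 and 9 (81) in DESeq2. The count was 13 without stage 2 replicate 1, and 8 and 0 without stage 1 replicates 2 and 3, where the lone stage 1 library is assumed to vary like the other groups. Without stage 1 replicate 2 the calls of Solyc03g098680, Solyc03g119620 and Solyc06g073750 were lost, and the last was also lost without any 1 stage 2 replicate. Without stage 1 replicate 3 each call named here was lost in edgeR. The call of Solyc07g053460 was also lost when only the 2 groups compared were fitted (edgeR adjusted p = 0.162).

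Between stages 2 and 3 of fertile buds, 2 of the 6 tested members of the tapetum and anther opening list were called by edgeR, and both fell. TomA108 fell from 579 ± 443 to 21.8 ± 18.5 CPM (n = 3 each), a log2 change of -4.63 (edgeR adjusted p = 0.0463). The aspartic proteinase gene fell from 1156 ± 1016 to 9.09 ± 7.32, a log2 change of -6.85 (edgeR adjusted p = 0.0385), though the groups overlapped: stage 2 replicate 2 lay at 7.34, below 16.6 and 8.66 in stage 3 replicates 1 and 3. Solyc01g010900 and Solyc03g116390 fell, with read ratios of 248 (84.5 to 1203) and 234 (64.5 to 1936). Solyc04g074340 rose from 4.39 ± 0.763 to 84.8 ± 69.1 (log2 4.22) and Solyc02g061770 from 10.9 ± 8.56 to 122.7 ± 91.2 (log2 3.48). In total 10 genes rose and 22 fell, 32 in edgeR, against 53 and 74 (127) with the replicate number as a block, 150 and 122 (272) with that block fitted within each line, and 49 and 36 (85) in DESeq2, so whether falls outnumber rises depends on the setting. The count was 2, 62 and 13 without stage 2 replicates 1, 2 and 3, and 76, 1 and 0 without stage 3 replicates 1, 2 and 3. Each of the 6 calls named was lost without stage 2 replicate 1 or stage 3 replicate 2 or 3. All but that of Solyc03g116390 were also lost without stage 2 replicate 3, those of Solyc03g116390 and the aspartic proteinase gene without stage 3 replicate 1, and that of Solyc02g061770 without stage 2 replicate 2. Over the alternatives the adjusted p of TomA108 and the aspartic proteinase gene reached 0.275 and 0.461.

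In sterile buds, the genes named here were chosen after their values were seen. Between stages 1 and 2 edgeR called 0 genes (927 at an unadjusted p under 0.05), DESeq2 41, and limma 2 with either pseudocount. With the replicate number as a block edgeR called 28, and 93 with that block fitted within each line. ARG2 stood at 71.4 ± 17.5 and then 399 ± 302 CPM (n = 3 each, edgeR adjusted p = 0.195), and CHS1 (Solyc09g091510), a chalcone synthase gene, at 209.5 ± 16.7 and then 364 ± 81.1 (edgeR adjusted p = 0.280). Without stage 2 replicates 2 and 3 in turn the count was 45 and 1. Between stages 2 and 3 edgeR called 0 genes (782 at an unadjusted p under 0.05), 0 with the replicate number as a block, 18 with that block fitted within each line, DESeq2 4 and limma 0. MYB21 (Solyc02g067760), a jasmonate-responsive MYB gene of late stamen development, stood at 13.95 ± 12.9 and then 125 ± 98.0 (edgeR adjusted p = 0.507).

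**Figure D3:**
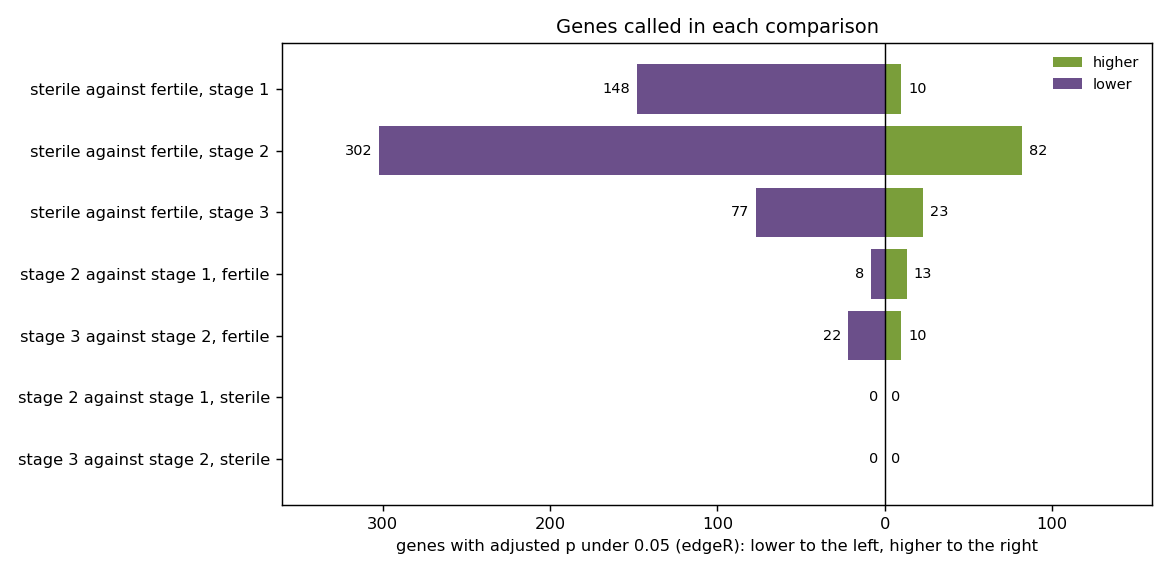
Number of genes with a Benjamini-Hochberg adjusted p under 0.05 in edgeR (horizontal axis) for 7 comparisons (vertical axis), lower genes to the left and higher genes to the right of 0. Stage 2 has 302 lower and 82 higher genes in sterile against fertile buds, and both consecutive-stage comparisons in sterile buds have 0.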

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

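The block within each line, the fit without the sterile libraries numbered 3, the thinning, the stage 3 against stage 1 comparison and the line average were chosen after the data were seen; the other alternatives were planned. Counts of sterile against fertile genes at stages 1, 2 and 3 (158, 384 and 100) became 425, 891 and 305 without the low-count filter and 293, 732 and 221 with a replicate block. They became 237 at stage 2 with only the groups compared, 179 at stage 3 with DESeq2, and 59 and 28 at stages 1 and 3 without the sterile libraries numbered 3. Leaving out 1 library gave 54 to 208, 164 to 398 and 13 to 129.

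In fertile buds the stage 2 against stage 1 and stage 3 against stage 2 counts (21 and 32) became 81 and 85 with DESeq2, 157 and 253 without the filter, 5 and 19 with only the groups compared, 81 and 127 with a replicate block, and 196 and 272 with a block within the line. With that block 150 of the 272 rose and 122 fell. The 2 pairs of fertile stages 1 and 2 had correlations of 0.308 and 0.294. Limma gave 47 for the first with pseudocount 1 and 8 for the second with 0.1, and leaving out 1 library gave 0 to 30 and 0 to 76. In sterile buds these counts (0 and 0 in edgeR, 927 and 782 at an unadjusted p under 0.05) became 41 and 4 with DESeq2, 89 and 45 without the filter, and 93 and 18 with a block within the line. The first also became 28 with a replicate block and 2 with limma at pseudocount 1 or 0.1, the second 1 with only the groups compared. Leaving out 1 library gave 0 to 45 and 0 to 0.

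Stage 3 against stage 1 (856 fertile, 280 sterile) became 1299 and 679 with a replicate block and 1762 and 1037 with a block within the line. In sterile buds it became 451 with DESeq2 and 528 without the filter. With limma the balance turned: 448 rose and 526 fell in fertile and 160 and 202 in sterile buds with pseudocount 1, and 383 and 424 in fertile but 144 and 142 in sterile buds with 0.1. Leaving out 1 library gave 83 to 750 and 18 to 474. The averaged line difference (1321) became 825 at 2-fold or more, and 865 to 1409 when leaving out 1 library. Stage dependence (0 in edgeR, 365 unadjusted) became 14 with DESeq2, 21 without the filter, 3 with a replicate block, 6 and 1 with limma at pseudocount 1 and 0.1, 8 with a block within the line, and 0 to 1 when leaving out 1 library. List calls (11) became 6 with an estimated correlation and 12 with a replicate block, where the jasmonate and wound list was lower at stage 1 (camera adjusted p = 0.0137 against 0.0661). Where fewer libraries were used the loss of samples is part of the change; otherwise the cause was not tested.

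For 48 pairs of named gene and comparison, 690 values under alternatives were compared: 550 kept direction and side of the threshold, 121 lost the threshold, 19 gained it and 0 reversed. Thinning to 499608 reads gave a median of 331.5 genes for stage 2, 29.5 for fertile stage 3 against stage 2 and 14 for fertile stage 2 against stage 1.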

Other observations

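The genes named below, the line difference averaged over stages, stage 3 against stage 1, the values without the low-count filter, the thinning, the block within each line, the splits of whole replicate sets, the test of stamen tissue, the tests of higher and of lower genes near Ms10, the scan along chromosomes and the distances other than 300 gene models were chosen after the result was seen. Averaged over the 3 stages, 1321 genes differed between the lines in edgeR, 473 higher and 848 lower in sterile buds. Of 8 identity genes 4 were lower over all genes and 6 when adjusted over the list alone, with log2 differences of -1.02 (SE 0.23) for TAP3, -0.999 (SE 0.17) for the PISTILLATA-type gene Solyc08g067230, -0.89 (SE 0.16) for TAG1 and -0.62 (SE 0.14) for TM5, a SEPALLATA-type gene (edgeR adjusted p = 0.00994, 0.00105, 0.00154 and 0.01). Of 9 flavonoid and anthocyanin genes 4 were higher over all genes, by a log2 difference of 3.30 (SE 0.53) for DFR, 1.75 (SE 0.33) for AN2, 0.53 (SE 0.14) for CHS1 and 0.49 (SE 0.15) for F3'H, a flavonoid hydroxylase gene (edgeR adjusted p = 0.000697, 0.00225, 0.0236 and 0.0484). Adjusted over the list alone, 5 were higher and 1 lower. The gibberellin gene PROCERA was higher only when adjusted over its list alone (log2 0.38, SE 0.15, edgeR adjusted p = 0.135 over all genes). Ms32 was lower on average (log2 -3.59, SE 0.84, edgeR adjusted p = 0.0130). Ms10 and MS1, with 0 reads in whole groups, could not be judged on average (SE 4481 and 23830). The count was 865 without fertile stage 1 replicate 2. Among 100 splits that exchange single libraries between lines within stages, 1 gave as many genes, the real one, and the highest other gave 289. These treat libraries of a line as independent, although those with the same number varied together across stages 2 and 3. With the 6 replicate sets kept whole over their stages, 1 of 10 splits gave as many genes, the real one, and the highest other gave 953, with sterile sets 1 and 2 and fertile set 1 on 1 side. These splits are too few for a share under 0.05.

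From stage 1 to stage 3, 856 genes changed in fertile buds (468 up, 388 down) and 280 in sterile buds (194 up, 86 down) in edgeR. Rises did not outnumber falls in every setting: with limma at pseudocount 1 it was 448 up and 526 down in fertile and 160 up and 202 down in sterile buds, and without fertile stage 1 replicate 2 it was 86 up and 179 down. Both lines shared 128 rising genes (6.69 expected from independent calls) and 58 falling genes (2.46 expected), though libraries numbered 3 shift alike in both lines and the calls are not independent, and 786 of the 856 fertile calls (91.8%) had the same sign in sterile buds. MYB21 rose in sterile buds from 1 read at stage 1 to 125 ± 98.0 CPM at stage 3 and in fertile buds from 0 reads to 286 ± 153 (edgeR adjusted p = 0.0149 and 0.00529). The threonine deaminase gene TD (Solyc09g008670) rose by a log2 change of 4.13 in sterile and 3.92 in fertile buds (edgeR adjusted p = 0.0253 and 0.0330), and ARG2 by 2.46 and 2.57 (edgeR adjusted p = 0.0467 and 0.0420). The small heat shock gene HSP21 (Solyc03g082420) fell by 2.81 on the log2 scale in sterile buds and fell by 4.04 in fertile buds (edgeR adjusted p = 0.0130 and 0.00266). TAG1 rose in fertile buds by 1.49 (edgeR adjusted p = 0.0101) and stood at 0.995 in sterile buds (edgeR adjusted p = 0.0607). The fertile count was 265 and 83 without stage 1 replicates 2 and 3, and 389 and 295 without stage 3 replicates 2 and 3. The sterile count was 70, 18 and 56 without stage 1 replicates 1, 2 and 3, and 23 and 474 without stage 3 replicates 1 and 3. For the sterile comparison, 1 of 10 splits of the 6 libraries gave as many genes as the real one, 239 with these libraries alone against 0 in the highest other, which is too few splits for a share under 0.05.

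Below the filter, LAT52, a late pollen gene, had 18 reads in fertile and 0 in sterile buds at stage 3 (edgeR adjusted p = 0.0473 without the filter). The anthocyanin transport gene AA (Solyc02g081340) had 14, 14 and 17 reads in sterile and 5, 2 and 0 in fertile buds at stages 1, 2 and 3. Sterile replicate 1 held 0 of these reads at stages 2 and 3, so the libraries of the lines overlapped there. The averaged log2 difference of AA without the filter was 3.12 (SE 0.73, edgeR adjusted p = 0.00357).

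Lower anther genes in sterile buds were weighed against depth and tissue makeup. Sterility and line coincide in these samples, so effects of other differences between the lines cannot be told apart from those of sterility. With all libraries thinned to 499608 reads, a median of 81.9% of stage 2 calls were lower in sterile buds (80.2% to 84.5% over 10 thinnings), so a difference in depth does not account for the direction. The anther and tapetum median of 11 genes differed by -6.75 log2 units from that of 4 petal and stamen identity genes at stage 2, or -4.39 with the 3 genes without sterile reads at their bound; petals also use the identity genes, so a lower share of stamen tissue and lower expression within it cannot be told apart. For stages 2 and 3, 1 of 10 splits of the 6 libraries gave as many genes as the real ones, 237 and 104 with these libraries alone against 0 in the highest other, too few splits for a share under 0.05. That loss of Ms10 function may lower these genes in the tapetum itself is a hypothesis that was not tested here. Their levels in tapetum isolated from both lines would show whether they are lower within that tissue. They would not tell loss of Ms10 from other differences between the lines.

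The line differences averaged over the stages could partly reflect a chromosome segment around Ms10 that came from another parent. Of the 1321 genes, 35 (2.65%) lay within 300 gene models of Ms10 against 2.20% of other tested genes (one-sided Fisher's exact p = 0.173). Most of the called genes thus lie outside this distance. Their position cannot tell whether a gene within the segment changes genes elsewhere, so the count does not exclude the segment as a source. Split by direction, 23 of 473 higher genes lay there (4.86% against 2.15%, exact p = 0.00044, adjusted p = 0.00132) and 12 of 848 lower genes (1.42% against 2.30%, exact p = 0.972). With distances of 100, 150 and 600 models the exact p was 0.00292, 0.0174 and 0.000684 for higher genes and 0.62, 0.481 and 0.589 for lower genes. A linked segment thus stays a candidate explanation for some higher genes, yet of 124 windows along the chromosomes 2 passed for higher genes, this one and 1 at the start of chromosome 1 (exact adjusted p = 0.0272 for both), so the excess is not unique to Ms10. Of the genes named here within 600 gene models of Ms10, AA (not among those counted) lies 153 models from it and DFR 518. The lower genes Solyc02g080760, Solyc02g078370 and TAG1 lie 95, 143 and 409 models from it. F3H, not called on average, lies 405 models from it.

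Few consecutive-stage changes were called in sterile buds (0 and 0 in edgeR, 927 and 782 at an unadjusted p under 0.05, 41 and 4 in DESeq2). The unadjusted counts are not counts of changed genes, since a share of 0.05 of the 13568 tested genes is expected without any change. Lower depth does not account for the 0 between stages 2 and 3: thinned to 499608 reads, fertile buds still gave a median of 29.5 genes there (21 to 34). Between stages 1 and 2 the thinned fertile count had a median of 14 (5 to 21), a range too wide to decide, so lower depth of the sterile libraries stays open for that comparison. Replicate sets that vary together may be part of both low counts. A block within each line gave 93 genes between stages 1 and 2 of sterile buds and 18 between stages 2 and 3. A replicate block over both lines gave 28 and 0. The block within each line also raised the fertile counts, from 21 to 196 and from 32 to 272. A slower change of the sterile buds themselves stays open. Between stages 1 and 3 of sterile buds edgeR called 280 genes, and 18 to 474 when leaving out 1 library. Some change over the whole span was thus called in each of these fits, though its extent is uncertain. Between stages 1 and 2 of sterile buds the real split gave 0 genes, so that 10 of 10 splits gave as many is fixed in advance and says nothing about chance. Apart from that, 1 split with stage 1 replicate 1 beside stage 2 replicates 1 and 2 gave 24 genes against 0 in the real one, which points to a structure of the samples.

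Between stages 2 and 3, 1 of 10 splits gave as many genes as the real one in either line, with the 6 libraries alone. In fertile buds the real split gave 19 and the highest other 13, and among the 4 splits that part every pair the highest other gave 0, while the rest part 1 pair. In sterile buds the real split gave 1 and the highest other 0. These splits are too few for a share under 0.05.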
